A study of Mus musculus with 5 samples.

How the data were processed

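RNA-seq was made from 5 libraries of OG2 mouse embryonic stem cells: 2 labelled siDhx30, 2 labelled siTfam and 1 labelled NC. Per the labels' protocols, total RNA was DNase-treated and fragmented, cDNA was made with a template-switching kit, and libraries were sequenced as read pairs. The submitters' processing notes name bcl2fastq, HISAT2, featureCounts and DESeq2 and the build GRCm38, with no settings or strand use. The authors deposited 1 table of log2 fold values per gene, 1 column for each of the 4 siRNA libraries, per the file headers. No count, level, p-value or NC column was used here, and no value column was left unused. The depth per library is unknown, so no counting interval is given. A ratio of low counts is noisy, and such genes could not be told from abundant ones.

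Upper-case gene names were matched to GENCODE M21 symbols on GRCm38: 12660 of 12930 matched, 166 matched RefSeq symbols and 104 matched neither. The sign of the deposited log2 values was inferred from the pattern of missing values, set beside simulated filters, and all values were turned to siRNA over NC. The 12088 genes with values in all 4 libraries were tested, and 842 genes with a missing value were left out of the main test.

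The comparisons and groups were fixed before the data were examined, with a count-based test for counts and, for a table of the authors' comparison columns alone, those columns as deposited with no test. The table held such columns, 1 per library. The limma test on them (limma 3.58.1 in R 4.3.3), and its use for the lists, were chosen after the table was seen and depart from that plan. The NC library, the denominator of every ratio, entered as a column of zeros, which equals a fit on log levels with 1 coefficient per group and 2 residual degrees of freedom. The NC library was assumed to vary like the siRNA libraries. Variances were moderated with robust=TRUE and without a trend on abundance, because abundance was unknown (prior degrees of freedom 2.02). Comparisons were siDhx30 against NC, siTfam against NC and siDhx30 against siTfam, with Benjamini-Hochberg adjustment and a threshold of 0.05.

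Of 24 gene lists, fixed at the same time as the comparisons, the 18 with 5 or more measured members were tested with camera at a preset correlation of 0.01, adjusted over lists within a comparison. The lists covered mitochondrial rRNA and tRNA, mitochondrial mRNA, nuclear OXPHOS subunits, mitochondrial and cytosolic ribosomal proteins, mitochondrial RNA processing, mitochondrial DNA maintenance, chaperones and proteases, the ATF4, p53, hypoxia and interferon responses, glycolysis, the TCA cycle, cholesterol synthesis, histones, and markers of naive, formative, streak, neural, primitive endoderm, trophoblast, 2-cell-like and feeder cells. The rule for named genes, fixed at the same time, was Dhx30 and Tfam, up to 4 members past the threshold from each list, and the 8 highest and 8 lowest genes past it with a proper symbol and both replicates on one side. Where fewer than 5 genes passed, the 5 smallest p were named as not passing, of which 1 in siDhx30 against siTfam is not used here. As no gene passed, the examples given from lists, and the genes shared by all 4 libraries, were chosen after their values were seen.

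The test was tried on simulated data in 5 runs per comparison, with 200 changed genes among 12088 and variances drawn from the fitted prior. False calls over the 5 runs numbered 21, 17 and 38 in the 3 comparisons in the order above. A planted list of up to 20 genes at a log2 change of 1 was called in 5 of 5 runs and an unchanged list in 0. Chance agreement through the shared control was simulated in 100 draws with each gene's own residual spread, and the count of genes in both comparisons was taken by the same test in each draw. The siRNA libraries were drawn independently of one another. Transcript length and GC content were taken from the longest GENCODE transcript (11859 tested genes had them), and trends were removed per library by a quadratic fit on log2 length and GC content, with their product, over 9256 protein-coding genes. Alternatives left out each siRNA library in turn, kept genes with missing values, left out mitochondrially encoded genes, used robust=FALSE or a fold threshold, restricted the libraries, blocked on the replicate number, and used an estimated correlation or fry for lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.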

Results

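RNA of mouse embryonic stem cells was measured after transfection of siRNAs against Dhx30 or Tfam. Dhx30 encodes an RNA helicase found at mitochondrial RNA granules, and Tfam encodes the transcription and packaging factor of mitochondrial DNA. The cells, of the OG2 line, were kept for 24 h in a medium that holds the naive state, then transfected at 50 nM siRNA while being moved for 36 h to a medium with bFGF and Activin A. The series holds 5 libraries: 2 labelled siDhx30, 2 labelled siTfam and 1 labelled NC, taken here as the control. The deposited values are 1 log2 ratio per gene for each of the 4 siRNA libraries, read here as being against the NC library. Of 12930 genes, 12088 had a value in all 4 libraries. Read totals are not given in the sources used here, so the depth behind each ratio is unknown. The labels do not say that the replicates were separate cultures. The limma p-values therefore measure only the spread between these libraries, which may be technical. The camera p-values at the preset correlation weigh list members against the other genes, and a small one is no measure of replication across libraries.

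All ratios below are given as siRNA over NC. The column headings state neither the direction nor the denominator, and the direction was inferred from which values were missing. All 1574 deposited values of genes with a missing value elsewhere were negative. All 102 genes with a deposited value above 3 were complete, against 20 of 124 genes below -3. The simulated filters all set a minimum on counts, and no other kind was tried. Among them, negative values alone arose only where either library had to reach a minimum and the ratio was NC over siRNA. The deposited signs were therefore turned round, and every direction below rests on that inference, which made no use of the targeted genes. The true filter is unknown: the pluripotency genes Pou5f1, Sox2 and Nanog were not found among the deposited gene names, and why was not tested. Once turned, the genes left out for a missing value had values above NC only. Counts of higher genes below therefore omit most of the largest increases.

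The targeted transcripts were examined first. Dhx30 (ENSMUSG00000032480.17; GRCm38 chromosome 9, 110084320 to 110117830, minus strand) had log2 ratios of -0.40 and -0.20 in the siDhx30 libraries, a mean of -0.30 (SE 0.20, n = 2), or 81.2% of the NC level. The 95% interval ran from 55.5% to 118.7%, and limma gave an adjusted p of 0.998. In the siTfam libraries Dhx30 lay at 0.01 and 0.04. Tfam (ENSMUSG00000003923.14; GRCm38 chromosome 10, 71225464 to 71238280, minus strand) had log2 ratios of -0.28 and -0.02 in the siTfam libraries, a mean of -0.15 (SE 0.22, n = 2), or 90.2% of NC. Its interval ran from 59.4% to 137%, with a limma adjusted p of 0.987. In the siDhx30 libraries Tfam lay at 0.12 and -0.01. Each target was lower than NC in both of its own libraries, but both 95% intervals included 0, and 18.6% of all genes had a lower ratio than Dhx30 in siDhx30. With the deposited sign kept, Dhx30 would lie at 123.2% of NC in siDhx30, with 81.4% of genes lower, and Tfam at 110.9% of NC in siTfam. The direct comparison of siDhx30 with siTfam, which does not involve the NC library, gave -0.33 for Dhx30 (95% interval -0.77 to 0.12) and 0.20 for Tfam (-0.29 to 0.69). The Tfam difference was 0.07 without siTfam replicate 1 and 0.33 without siTfam replicate 2. The Dhx30 difference was -0.22 without siDhx30 replicate 1 and -0.43 without siDhx30 replicate 2. A knockdown at the RNA level was therefore not established for either gene.

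**Figure D1:**
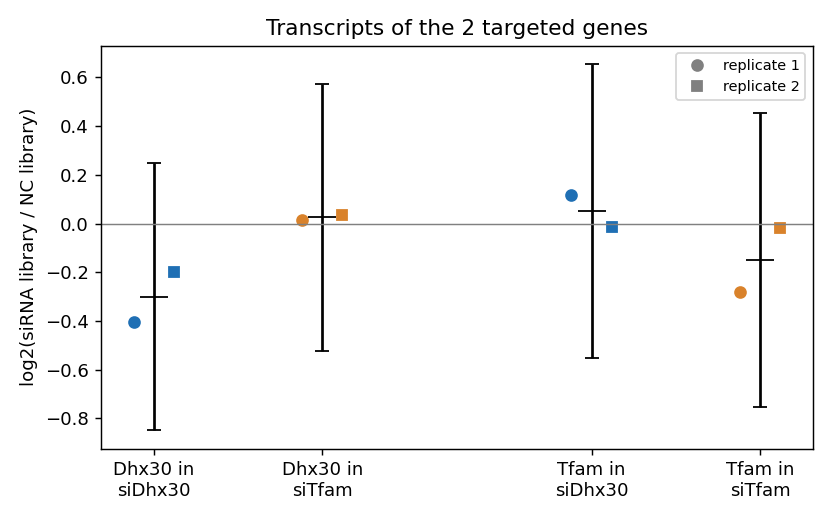
Log2 ratio to the NC library (vertical axis) of Dhx30 and Tfam in the siDhx30 (blue) and siTfam (orange) libraries. Points are single libraries, horizontal bars are means of 2 libraries and vertical bars are 95% intervals of the limma fit; Dhx30 averaged -0.30 in siDhx30 and Tfam -0.15 in siTfam, and all 4 intervals include 0.

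Against NC, the hypoxia response genes were the list that passed in the siDhx30 libraries, where they rose as a list. Of 11 measured members 10 had a positive ratio, with a median of 0.27 (camera with a preset correlation, adjusted p = 0.0363). With an estimated correlation, of 0.236, the camera adjusted p was 0.953. Ndrg1, a stress-responsive gene, lay at 1.31 in both siDhx30 libraries, and Bnip3, a mitophagy receptor, at 0.55 and 0.87. The list median was 0.10 in replicate 1 and 0.56 in replicate 2, and without replicate 2 the adjusted p was 0.723. It was 0.0854 at the same median without siTfam replicate 1 or 2, which serve here only to estimate the spread. The list leaned the same way in siTfam against NC, with 9 of 11 positive and a median of 0.15 (adjusted p = 0.0953), and siDhx30 and siTfam were not shown to differ in it (median difference 0.11, adjusted p = 0.372; -0.14 without siDhx30 replicate 2). No member passed, either over all genes or adjusted over the list alone.

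No single gene passed an adjusted p of 0.05 in siDhx30 against NC. The limma count was 0 of 12088 genes, with 609 genes at an unadjusted p under 0.05 (310 higher, 299 lower) where 604.4 are expected by chance. The 5 genes with the smallest p, none passing, were Arhgef17 at -4.37 (SE 0.23), the long non-coding RNA AI838599 at -4.74 (SE 0.25), Acsf2, an acyl-CoA synthetase family member, at -2.96 (SE 0.23), Pip5kl1 at 2.80 (SE 0.22) and the retinol dehydrogenase gene Rdh13 at -2.60 (SE 0.21). The smallest adjusted p was 0.298. On simulated data of the same size with 200 changed genes planted, this test recovered 0% of genes changed by 1 on the log2 scale, 8.8% by 2, 54.8% by 3 and 70% by 4. At best, only very large changes were detectable. With fewer changed genes the adjusted threshold is harder to pass, so these shares may be too high for the real data. Arhgef17 and AI838599 did not pass, although their SEs were close to the median over all genes, 0.25.

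Against NC, the siTfam libraries had higher ratios for nuclear-encoded subunits of the respiratory chain and for cytosolic ribosomal proteins, and lower ratios for primitive endoderm markers. Of 55 nuclear OXPHOS subunits 43 were positive, with a median of 0.21 (camera adjusted p = 0.000641; adjusted p = 0.561 with an estimated correlation). The complex I subunit gene Ndufa12 lay at 0.70 and 0.61 and Ndufa11 at 0.52 and 0.67. Of 65 cytosolic ribosomal protein genes 45 were positive, with a median of 0.09 (camera adjusted p = 0.00903; adjusted p = 0.561 with an estimated correlation). All 7 measured primitive endoderm genes were negative, with a median of -0.38 (camera adjusted p = 0.0192; adjusted p = 0.561 with an estimated correlation). Other listed primitive endoderm genes had a missing value and were left out. Values of such genes lay only above NC as turned here, so the filter could remove higher members alone, and the shared sign is partly its product. The estimated correlations of these lists were 0.001, 0.005 and -0.029 in that order, below the preset 0.01. A higher correlation was therefore not why these calls ended: that version of camera works with only the 2 residual degrees of freedom. Dab2, an endocytic adaptor, lay at -1.62 and -1.30, and the collagen IV gene Col4a2 at -1.05 and -2.21. The ribosomal protein median was 0.05 (adjusted p = 0.32) without siTfam replicate 2 and 0.22 without siTfam replicate 1. Without siTfam replicate 2 the primitive endoderm median was -0.39, no smaller than with it, at an adjusted p of 0.12. The ATF4 and integrated stress response list had a median of 0.13 with 22 of 32 members positive and missed the threshold (adjusted p = 0.0508; adjusted p = 0.941 with an estimated correlation). At the preset correlation it passed with mitochondrially encoded genes left out (0.0483), with centring (0.0486), among protein-coding genes (0.0121) and with length and GC trends removed (0.0147), and not without siTfam replicate 1 (0.382) or 2 (0.0828). Leaving out mitochondrially encoded genes, or keeping only protein-coding genes, also took the mitochondrial rRNA and tRNA list out of the adjustment. Fewer lists lower an adjusted p at the same unadjusted p, which matters this near the threshold. Trends with transcript properties bear on the lists of this comparison: across 9256 protein-coding genes, the ratio of siTfam replicate 2 had a Spearman correlation of -0.18 with transcript length, and that of replicate 1 one of -0.24 with GC content. With both trends removed the OXPHOS median went from 0.22 among protein-coding genes to 0.14 (adjusted p = 0.0147), the ribosomal protein list had a median of 0.02 (adjusted p = 0.237) and the primitive endoderm list one of -0.23 (adjusted p = 0.061).

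Single genes again did not pass: the limma count was 0 of 12088 for siTfam against NC, with 739 genes at an unadjusted p under 0.05 (367 higher, 372 lower). The 5 smallest p belonged to Arhgef17 at -4.41 (SE 0.23), AI838599 at -4.79 (SE 0.25), 4930415C11Rik at -2.33 (SE 0.18), Rdh13 at -2.75 (SE 0.21) and Acsf2 at -2.93 (SE 0.23), and the smallest adjusted p was 0.285. 4930415C11Rik is annotated as antisense, and its reads cannot be told from those of an overlapping gene without strand. The simulated recovery for this comparison, again with 200 planted genes and the same limit, was 0% at a log2 change of 1, 6% at 2, 55.2% at 3 and 72% at 4.

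The direct comparison of the siRNAs was the only one with 2 libraries on each side. Cytosolic ribosomal protein genes fell as a list in siDhx30 relative to siTfam: 61 of 65 were lower, with a median of -0.16 (camera adjusted p = 1.58e-05; adjusted p = 0.369 with an estimated correlation). Nuclear OXPHOS subunits were lower in 45 of 55 cases, median -0.16 (adjusted p = 0.000562; adjusted p = 0.369 with an estimated correlation), among them Ndufa12 at -0.45 (SE 0.17). Of 32 ATF4 and integrated stress response genes 26 were lower, median -0.14 (adjusted p = 0.000562; adjusted p = 0.727 with an estimated correlation), such as the asparagine synthetase gene Asns at -0.38 (SE 0.16). Mitochondrial ribosomal proteins were lower in 51 of 65 cases, median -0.09 (adjusted p = 0.0136; adjusted p = 0.775 with an estimated correlation). The 7 primitive endoderm genes were all higher, median 0.40 (adjusted p = 0.00516; adjusted p = 0.473 with an estimated correlation). The estimated correlation was 0.147 for ATF4 genes and 0.244 for mitochondrial ribosomal proteins, above the preset 0.01. It was 0.005, 0.001 and -0.029 for cytosolic ribosomal proteins, OXPHOS and primitive endoderm, so a higher correlation did not end those calls. No member of these lists passed by itself, over all genes or adjusted over the list alone.

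Several of these lists changed when a library was left out or when trends with transcript properties were removed. The ATF4 list had a median of -0.05 (adjusted p = 0.217) without siDhx30 replicate 1. Without siTfam replicate 1 its adjusted p was 0.224 at a median of -0.15, no smaller than with it, and the median was -0.25 without siDhx30 replicate 2 and -0.22 without siTfam replicate 2. Its median difference was -0.24 between the libraries numbered 1 and -0.0068 between those numbered 2. The same 2 medians were -0.02 and -0.14 for mitochondrial ribosomal proteins (34 and 50 of 65 lower), -0.09 and -0.21 for OXPHOS, -0.12 and -0.19 for cytosolic ribosomal proteins, and 0.26 and 0.51 for primitive endoderm. The mitochondrial ribosomal protein list had a median of -0.06 (adjusted p = 0.262) without siDhx30 replicate 1, 0.02 (0.926) without siTfam replicate 2 and -0.18 without siTfam replicate 1. The OXPHOS list had a median of -0.09 (0.0511) without siDhx30 replicate 2. The primitive endoderm list had one of 0.24 (0.116) without siTfam replicate 2 and 0.26 (0.045) without siDhx30 replicate 1. The cytosolic ribosomal protein list had one of -0.11 (0.0265) without siTfam replicate 2. With length and GC trends removed, OXPHOS had an adjusted p of 0.138 and mitochondrial ribosomal proteins 0.462, whereas cytosolic ribosomal proteins had 0.0484, ATF4 genes 0.00112 and primitive endoderm genes 0.0243.

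**Figure D2:**
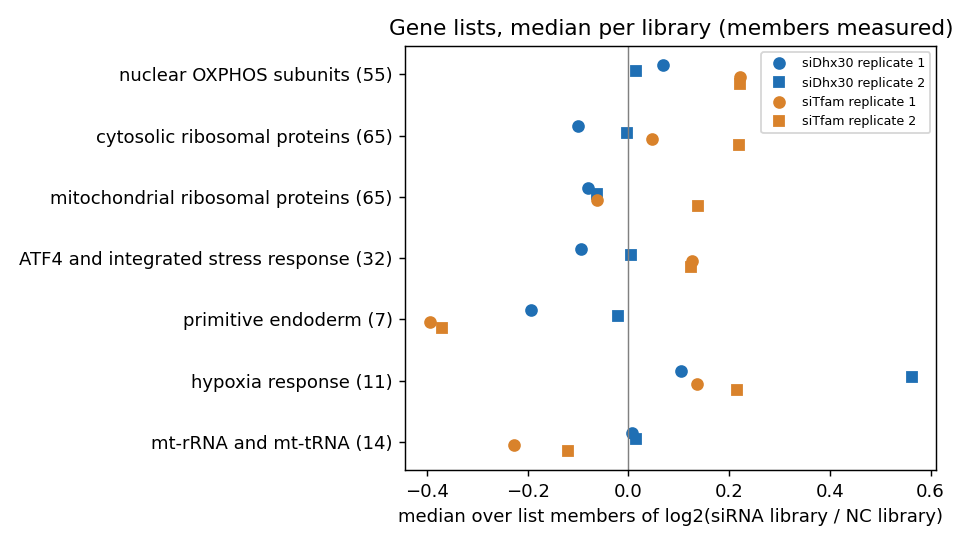
Median log2 ratio to the NC library (horizontal axis) over the measured members of 7 gene lists, 1 point per library (blue siDhx30, orange siTfam; circles replicate 1, squares replicate 2). Nuclear OXPHOS subunits sat at 0.22 in both siTfam libraries and at 0.07 and 0.02 in the siDhx30 libraries, while hypoxia genes reached 0.56 in siDhx30 replicate 2 against 0.10 in replicate 1.

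No single gene passed between siDhx30 and siTfam. The limma count was 0 of 12088, with 337 genes at an unadjusted p under 0.05 (156 higher, 181 lower), fewer than the 604.4 expected by chance. Among the genes with the smallest p were 4930415C11Rik at 1.70 (SE 0.15), Apba2 at 1.45 (SE 0.15), the zinc transporter gene Slc39a8 at 1.44 (SE 0.15) and 1700110I01Rik at 3.54 (SE 0.39), each with an adjusted p of 0.999. The simulated recovery here, again with 200 planted genes and the same limit, was 0% at a log2 change of 1, 37.6% at 2, 71.6% at 3 and 87.2% at 4.

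Transcripts made in mitochondria were covered by 14 rRNA and tRNA genes. None of the listed mitochondrial mRNAs was found among the deposited gene names, and why was not tested. The values below therefore do not speak for those mRNAs. The median log2 ratio of the 14 genes was -0.07 in siDhx30, with 7 of 14 positive, and -0.23 in siTfam, with 4 of 14 positive (camera adjusted p = 0.951 and 0.603). In siDhx30 the camera direction was upward although the median was negative, and the median was 0.02 without siDhx30 replicate 1 and 0.0070 without siDhx30 replicate 2. The siTfam median was -0.12 without siTfam replicate 1 and -0.23 without siTfam replicate 2. The large rRNA mt-Rnr2 lay at -0.57 and -0.34 in siDhx30 and at -0.53 and -0.28 in siTfam, and the small rRNA mt-Rnr1 at -0.27 and -0.14, and -0.09 and -0.04. Neither passed, with limma adjusted p from 0.928 to 0.998 against NC. The siDhx30 to siTfam difference of the list had a median of 0.08 (camera adjusted p = 0.265; adjusted p = 0.775 with an estimated correlation). That median was 0.42 without siTfam replicate 2, -0.06 without siTfam replicate 1, 0.25 without siDhx30 replicate 1 and -0.02 without siDhx30 replicate 2.

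Lists that passed elsewhere did not pass in siDhx30 against NC: the medians were 0.06 for nuclear OXPHOS subunits, -0.07 for cytosolic and -0.07 for mitochondrial ribosomal proteins, -0.01 for ATF4 genes and -0.16 for primitive endoderm. In siDhx30 replicates 1 and 2 the primitive endoderm median was -0.19 and -0.02, the OXPHOS median 0.07 and 0.02, and the cytosolic ribosomal protein median -0.10 and -0.0036. In siTfam against NC mitochondrial ribosomal proteins had a median of 0.04 and did not pass. The remaining lists did not pass in any comparison of all 5 libraries and all genes. In siDhx30 and siTfam against NC, respectively, the medians were 0.0087 and -0.02 for mitochondrial RNA processing genes, 0.06 and -0.04 for mitochondrial DNA maintenance, -0.07 and -0.09 for mitochondrial chaperones and proteases, and -0.0052 and 0.04 for the TCA cycle. They were -0.10 and 0.17 for naive pluripotency, 0.13 and 0.15 for formative and primed epiblast, 0.01 and 0.03 for p53 targets, 0.10 and 0.10 for glycolysis, -0.17 and -0.09 for the interferon response, 0.05 and -0.07 for cholesterol synthesis, and -0.59 and -0.32 for fibroblast and feeder markers. Of 22 naive genes 9 were measured, without Pou5f1, Sox2, Nanog, Klf4 or Zfp42. Of 23 formative genes 11 were measured, without Fgf5 or Pou3f1. These medians therefore do not show whether the pluripotent state changed. The feeder median was -0.23 and -0.62 in siDhx30 replicates 1 and 2, and -0.21 and -0.15 in those of siTfam. For mitochondrial RNA processing in both comparisons, and for the TCA cycle in siDhx30, the camera direction was opposite to the median, as it was for mitochondrial chaperones and proteases (median -0.0054) and the interferon response (0.0064) in siDhx30 against siTfam. At the preset correlation, glycolysis in siDhx30 against NC passed without siDhx30 replicate 1 (median 0.20, adjusted p = 0.0186) and with length and GC trends removed (0.14, 0.0337), and was -0.03 without siDhx30 replicate 2; with all libraries and an estimated correlation its adjusted p was 0.953. In siDhx30 against siTfam its median was 0.09, 0.18 (adjusted p = 0.0413) without siDhx30 replicate 1 and -0.08 without siDhx30 replicate 2, with an adjusted p of 0.775 at an estimated correlation and all libraries. Naive pluripotency turned to 0.02 in siDhx30 without siDhx30 replicate 2 and to -0.11 in siTfam without siTfam replicate 1. Against NC the median also changed sign for mitochondrial RNA processing, p53 targets and cholesterol synthesis without siDhx30 replicate 2, and for ATF4 genes, the TCA cycle and chaperones without siDhx30 replicate 1. In siTfam it did so for mitochondrial RNA processing without siTfam replicate 1, and for the TCA cycle and mitochondrial ribosomal proteins without siTfam replicate 2. Too few members were measured to test primitive streak genes (2 members, medians -0.68 and -0.59), neural genes (3, -0.57 and -0.07), trophoblast genes (2, 0.50 and 0.70) and 2-cell-like genes (1, -0.04 and -0.38). In replicates 1 and 2 the 2-cell-like gene lay at 0.29 and -0.37 in siDhx30, and at -0.98 and 0.23 in siTfam. The neural median was 0.03 and -0.16 in those of siTfam, and the streak median -1.02 and -0.33 in those of siDhx30. Histone genes were not analysed, since none of the names listed was found among the deposited gene names.

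Both siRNAs were compared with the same NC library, and their mean log2 ratios went together across genes (Pearson 0.748, Spearman 0.675; genes are not independent replicates). Unchanged siRNA groups simulated against a single shared control gave 0.668 (0.631 to 0.696 over 100 draws) and 0.606 (0.578 to 0.626). The covariance was 0.197 against a simulated 0.164 (0.145 to 0.181), a difference of 0.032, so all 3 lay above the simulated ranges. In the simulation the siRNA libraries shared nothing but the control, whereas the libraries numbered 1 correlated at 0.787. The ranges leave out anything those libraries share, so the excess cannot be assigned to the siRNAs. No gene was called by limma in both comparisons. At an unadjusted p under 0.05, 211 genes were higher and 179 lower in both. The simulated unchanged groups gave 103 to 175 higher and 114 to 186 lower, so the lower count lay within what the shared control alone gives and the higher count above it. The single control could not be split. Libraries of one siRNA resembled each other no more than those of the other siRNA: the correlation was 0.538 within siDhx30 and 0.528 within siTfam, against 0.787, 0.509, 0.488 and 0.546 between them, the highest being between the libraries numbered 1.

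In all 4 siRNA libraries 196 genes lay beyond 1 on the log2 scale on the same side of NC, 94 higher and 102 lower, a rule set after the values were seen. Of these, 97 were among the 9256 protein-coding genes (33 higher, 64 lower), so genes of other classes met the rule more often. The examples below are all protein coding. Genes with a missing value could not meet the rule, and all their values lay above NC as turned here, so the higher and lower sides were not counted alike. The simulated unchanged groups, with siRNA libraries drawn independently, gave 98 to 136 genes that met the rule. Arhgef17 averaged -4.39 (SD 0.14 over 4 libraries) and the macrophage mannose receptor gene Mrc1 -3.81 (SD 0.49). Of the lists, the 196 included 1 of 27 mitochondrial RNA processing genes, Grsf1, an RNA-binding protein of mitochondrial RNA granules, at -1.38 (SD 0.24). They also included 1 of 65 mitochondrial ribosomal protein genes, Mrpl42, at -1.82 (SD 0.18). The rule was met by 196 of 12088 genes, and by 97 of 9256 protein-coding genes. Among the higher genes were Nmbr, a bombesin-type receptor, at 3.55 (SD 0.36), Lars2, the mitochondrial leucyl-tRNA synthetase, at 1.26 (SD 0.17), and Lats2, a Hippo pathway kinase, at 2.01 (SD 0.45). The siDhx30 and siTfam libraries share this difference from NC, and with 1 NC library it has no replicate check on the control side.

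**Figure D3:**
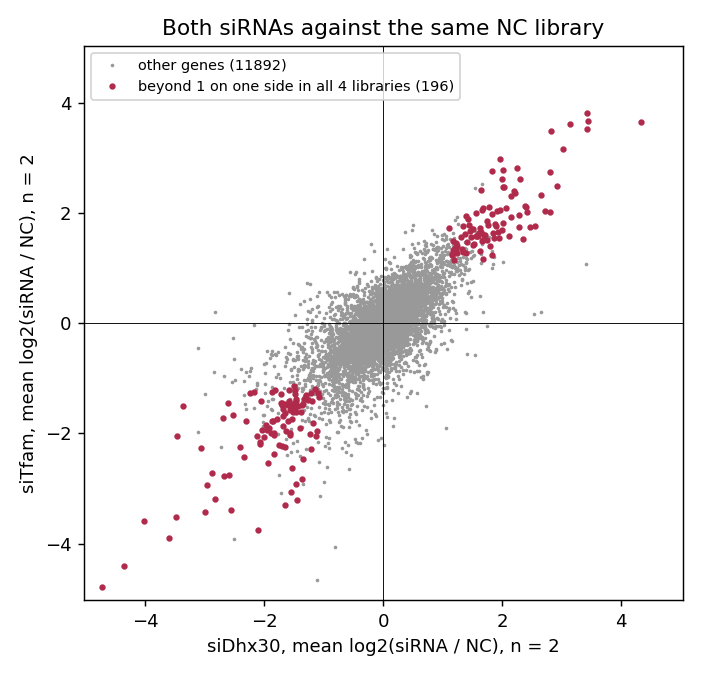
Mean log2 ratio to the NC library in siDhx30 (horizontal axis, 2 libraries) and siTfam (vertical axis, 2 libraries), 1 point per gene. The 196 genes beyond 1 on the same side in all 4 libraries are in red. The correlation over all 12088 genes was 0.748, against 0.668 in unchanged groups simulated with independent siRNA libraries.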

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

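Centring, removal of length and GC trends, pooling of both siRNAs and, for lists, all alternatives but the block, the estimated correlation and fry were chosen after seeing the data, as were some for the targets, the mitochondrial transcripts and the correlation. Counts of single genes stayed at 0 by limma in all 3 comparisons under every alternative run, with 279 to 979 genes at an unadjusted p under 0.05 when 1 siRNA library was left out, and 0 genes called in both comparisons against NC. With both siRNAs pooled against NC, limma called 2 genes, Arhgef17 and AI838599 (smallest adjusted p 0.0178; 823 genes at an unadjusted p under 0.05), and 0 without any 1 of the 4 libraries; the cause was not tested. Size factors, count-based Wald tests, pseudocounts, filters on mean level, other library sizes and CPM were planned and not run, since the table holds ratios only. An arm left with 1 library was assumed to vary like the others. Unknown depth limits all of these results.

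The number of lists called, 1, 3 and 5 in siDhx30 against NC, siTfam against NC and siDhx30 against siTfam, was 0, 0 and 0 both with an estimated correlation and with fry. In siDhx30 against NC it was 0 in a fit of only the libraries compared and 2 with length and GC trends removed, and ranged from 0 to 2 without each siRNA library. In siTfam against NC it ranged from 1 to 3 without each library, was 4 with mitochondrially encoded genes left out, with centring and among protein-coding genes, the fourth being the ATF4 list, and 2 with trends removed. In siDhx30 against siTfam it was 3 with trends removed and 4 without any 1 library, though not of the same lists: 3 of the 5 stayed without siDhx30 replicate 1, with glycolysis added, and 3 without siTfam replicate 2, with the mitochondrial rRNA and tRNA list added. The mitochondrial rRNA and tRNA median turned to 0.015 and 0.0070 in siDhx30 against NC without siDhx30 replicate 1 and 2, and ranged from -0.074 to 0.015. In siDhx30 against siTfam it ranged from -0.062 without siTfam replicate 1 to 0.42 without siTfam replicate 2, with -0.02 without siDhx30 replicate 2. With all libraries the list had a camera adjusted p of 0.265 at the preset correlation and 0.775 at an estimated one. The mitochondrial ribosomal protein median in siDhx30 against siTfam turned to 0.024 without siTfam replicate 2 and was -0.18 without siTfam replicate 1. The correlation of the siRNAs ranged from 0.569 to 0.756 without each library, lowest without siTfam replicate 1. The cause was not tested for any of these. Where mitochondrially encoded genes were left out or only protein-coding genes kept, the adjustment also lost the mitochondrial rRNA and tRNA list. Dhx30 in siDhx30 ranged from -0.40 to -0.20 and Tfam in siTfam from -0.28 to -0.02, with no adjusted p past the threshold.

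With the replicate number as a block, siDhx30 against siTfam gave 0 genes (566 at an unadjusted p under 0.05, smallest adjusted p 0.886) and 5 lists, so no call changed. The differences of replicate 1 from replicate 2 correlated at 0.254 between the siRNAs, over 2 pairs only, and the labels name no shared batch, so the numbers were not read as pairs and a shared batch stays open. Among the genes with the 5 smallest p and the lists called, 33 values lost their call, 1 turned its sign and 239 kept direction and side of the threshold. Those genes did not pass in the main fit, so only the lists had a call to lose, and the 239 are no measure of stability. For the targets, mitochondrial transcripts, counts and correlation, 4 values turned their sign, all of the mitochondrial transcripts given above, and 1 gained a call. A further 16 counts or correlations moved beyond a set margin, and 137 values stayed as they were.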

Other observations

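Tests on the 5 lists, on the spread of the NC library and on 3' UTR matches were chosen, or their criteria set, after the results were seen. Of other transcript classes, 470 long intergenic RNAs had medians of 0.20 and 0.18 in the siDhx30 and siTfam libraries numbered 1, and -0.05 and -0.0086 in those numbered 2. Processed pseudogenes (385) had 0.11, -0.09, 0.22 and 0.20 in siDhx30 replicates 1 and 2 and siTfam replicates 1 and 2. Of chromosomes with 100 or more protein-coding genes, X (267 genes) had medians of 0.12 and 0.08 in siDhx30 and siTfam replicate 1, and 0.03 and 0.01 in those numbered 2. Chromosome 17 (466 genes) had -0.11 and -0.04, and -0.02 and -0.02.

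Lists differed between siDhx30 and siTfam, and a trend with transcript length and GC content may account for part of them. Once each library's trend was removed, the OXPHOS median went from -0.16 to -0.05 (interquartile range 0.22 before, 0.20 after; adjusted p = 0.138), and that of mitochondrial ribosomal proteins from -0.09 to -0.02 (interquartile range 0.14 before, 0.15 after; adjusted p = 0.462): their calls ended because the medians shrank at a similar spread. Cytosolic ribosomal proteins went from -0.16 to -0.07 with an adjusted p of 0.0484, too near the threshold to decide. The ATF4 list stayed at -0.13 (adjusted p = 0.00112) and primitive endoderm went from 0.40 to 0.31 (adjusted p = 0.0243), against the trend as their whole cause. These values use the preset correlation, an effect of the siRNAs stays open and untested beyond it, and no list passed with an estimated one. The estimated correlation lay above the preset for ATF4 genes and mitochondrial ribosomal proteins, and below it for OXPHOS, cytosolic ribosomal proteins and primitive endoderm.

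The 196 genes beyond 1 on the same side of NC in all 4 libraries may reflect a response common to any active siRNA, or the NC library itself. The count exceeded the simulated 98 to 136, but that range assumes that NC varies like the siRNA libraries, and with 1 NC library these cannot be told apart. The range also assumes that the siRNA libraries vary independently, whereas the pair numbered 1 correlated at 0.787, above every other pair. Length and GC trends did not account for the protein-coding part of the count, since 97 such genes before and 101 after removal met the rule. Trends were not removed from genes of other classes, so for those this was not tested. Shared siRNA seed matches were sought as 7-mers in 9057 3' UTRs: the largest absolute z was 4.41, reached in 19 of 100 permutations (95th percentile 4.72), so no 7-mer stood out. The siRNA sequences were not used here, and a shift of up to 0.18 per 7-mer remained within the bounds, so this stays open.

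The libraries numbered 1 of both siRNAs resembled one another more than any other pair. Both had ratios that fell with GC content (Spearman -0.33 and -0.24, against -0.08 and -0.07 in those numbered 2), which made a composition trend a candidate explanation. With length and GC trends removed, the pair still correlated at 0.778, against 0.570 for the next pair, so that trend was not the whole cause. A shared culture or preparation day stays open, since the labels name no batch.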
